A study of Mus musculus with 28 samples.

How the data were processed

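Total RNA from 7 groups of mouse cells of C57BL/6 background was measured on Illumina beadchips, with 4 arrays in each group and 28 arrays in all. Donor cells of 3 kinds were profiled, namely hepatocytes, hepatoblasts taken from pooled fetal livers at embryonic day 16.5 with an E-cadherin antibody on magnetic beads, and embryonic fibroblasts. Induced pluripotent stem cells (iPSC) made from each donor kind with a lentivirus carrying reprogramming factors, and embryonic stem cells (ESC), were the other groups. Per the labels, infected cells were replated at day 7, 200 ng of RNA was amplified, and 750 ng of biotinylated cRNA was hybridised for 18 h at 58 °C. The iPSC and ESC arrays are described as independent biological replicates sorted on magnetic beads. Nothing in the labels states that the donor arrays came from separate animals, so p-values for donor groups measure the spread between these samples.

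The authors deposited, for each array, an intensity per probe that was not normalized between arrays, together with a detection p-value. The intensity values are background-subtracted, since 23.7% to 30.6% of them per array were negative. The submitters' processing notes name GenomeStudio 2009.1. The authors also deposited a second intensity table per array, which by its values is linear, quantile-normalized between arrays and not centred per gene. Its method is not given in the sources used here, and because the arrays carry 1 colour no direction of a ratio applies. Its columns ranked the probes as the first table did (lowest rank correlation 1), with column medians between 15.3 and 15.7.

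The first intensity table was used for all main values. Background was corrected and arrays were quantile-normalized with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16 and the negative-control distribution inferred from the detection p-values. Of 25697 probes, 16454 were kept because their detection p was below 0.05 on at least 4 arrays. Symbols of 20733 probes were current in the RefSeq gene table for GRCm38.p6, 3903 were renamed through a synonym, and 1061 kept the symbol of the file. That table served for names and for the order of genes on chromosome 11. The chromosome of each gene was taken from the deposited file. Genes without an entry there, such as Sox2 and Col1a1, were members of no chromosome set. Each gene was represented by its brightest kept probe, which gave 11901 genes. In 3191 genes there was more than 1 kept probe, and between 0 and 20 of these genes per comparison had probes called in opposite directions.

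Group means were fitted with limma over all 28 arrays (21 residual degrees of freedom) with a mean-dependent prior variance, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called when its adjusted p was below 0.05 and its fold at least 2. Differences are given on the log2 scale as the first group minus the second, with ± for the standard error, n = 4 arrays per group. Where no array of a group detected a gene, the change is given as "at least" a fold. That bound set the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest detected signal and the gene's own value.

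Before the data were examined, the groups, the 12 comparisons, the tests, the rule for naming genes, the processing alternatives and 25 gene lists with 554 entries were fixed. The lists covered pluripotency, germline, two-cell stage, trophoblast, mesoderm, endoderm, ectoderm and neural, epithelial, fibroblast and matrix, mature hepatocyte, hepatoblast and fetal liver, liver transcription factors, stellate and bile duct, endothelial, erythroid, macrophage and other leukocyte, imprinted, sex-linked, interferon response, p53 targets, immediate early and stress, glycolysis and hypoxia, cholesterol and lipid synthesis and cell cycle genes. The last list held only Nnt, which had no kept probe and was not tested. Of the entries, 430 were tested, and 23 lists had at least 5 members tested. Lists were tested with camera of limma against all other genes, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Each test was repeated with a correlation estimated from the data.

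Named genes were, in each comparison of iPSC with ESC or between iPSC, the 8 with the largest rise and the 8 with the largest fall. In each comparison with donor cells they were the top 5 in each direction. Only called genes whose arrays in the groups compared did not overlap were eligible, and symbols of predicted models were passed over. To these were added up to 4 members per list, the 6 most raised retained genes per donor and a fixed set of marker genes.

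A donor signature was the set of genes called higher in a donor group than in each of the other 2 donor groups. A shared hepatic signature held genes called higher than in fibroblasts in both hepatocytes and hepatoblasts. Signatures came from donor arrays and were tested on iPSC arrays, by camera and by an exact two-sided permutation test of the mean signature level per array. Genes called against ESC in both a donor and its iPSC were counted as retained and set beside the count expected if the calls were independent. Since the ESC arrays entered both comparisons, the counts were repeated with the ESC arrays split 2 against 2, and unchanged groups were simulated 20 times.

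The steps were tested on simulated data. In hepatoblast-iPSC against fibroblast-iPSC (11901 genes), changes were added to 50 genes per size. Genes changed 1.5-fold were called in 2 cases, 2-fold in 20, 3-fold in 49 and 4-fold in 50, with 1 false call. In hepatocyte-iPSC against the other 2 kinds of iPSC, camera on a set of 1000 genes returned a p of 0.014 for an added log2 shift of 0.05 and of 6.35e-10 for 0.1. The simulated genes varied independently and no other gene differed between groups. The real signatures had estimated inter-gene correlations of 0.0145 to 0.0228, so these p-values overstate what camera can find in real sets. The hepatocyte signature, with a mean difference of 0.115, gave a camera p of 0.0468.

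Alternatives were quantile normalization without background correction, a shift of arrays to a common 75th percentile, the authors' normalized values, other probe filters, the mean of all probes of a gene, fits on the compared arrays alone, no variance trend, array weights, other thresholds, a replicate block and leaving out each array in turn. A fit without ESC array 1 and fibroblast array 2 was added after the data were seen. The number of arrays limits the precision, and dim transcripts are limited by the background of the beadchip.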

Results

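Gene expression was compared between 3 kinds of donor cell of the mouse, the induced pluripotent stem cells (iPSC) made from each of them, and embryonic stem cells (ESC). The donor cells were hepatocytes, hepatoblasts (the fetal liver progenitors of hepatocytes and bile duct cells) and embryonic fibroblasts. The iPSC are named below after their donor as hepatocyte-iPSC, hepatoblast-iPSC and fibroblast-iPSC. The title of the series names the question, which was whether iPSC keep a memory of the donor that depends on its stage of differentiation. Each of the 7 groups had 4 arrays. The share of probes detected was lowest in hepatocytes, at 42.4% ± 0.380 (SD, n = 4), and highest in fibroblasts, at 50.9% ± 1.43. It was 47.4% ± 0.614 in hepatoblasts, 49.7% ± 0.742 in hepatocyte-iPSC, 48.8% ± 1.89 in hepatoblast-iPSC, 48.2% ± 1.18 in fibroblast-iPSC and 48.6% ± 1.99 in ESC. The median signal per array before normalization ranged from 7.55 to 29.7. On the first 2 principal components of all arrays, which carried 57.4% and 21.8% of the variance, the donor groups lay apart from each other and from the pluripotent cells. Among the pluripotent arrays alone, hepatocyte-iPSC lay apart on the components with 42.4% and 19.3% of the variance, whereas hepatoblast-iPSC and fibroblast-iPSC overlapped.

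**Figure D1:**
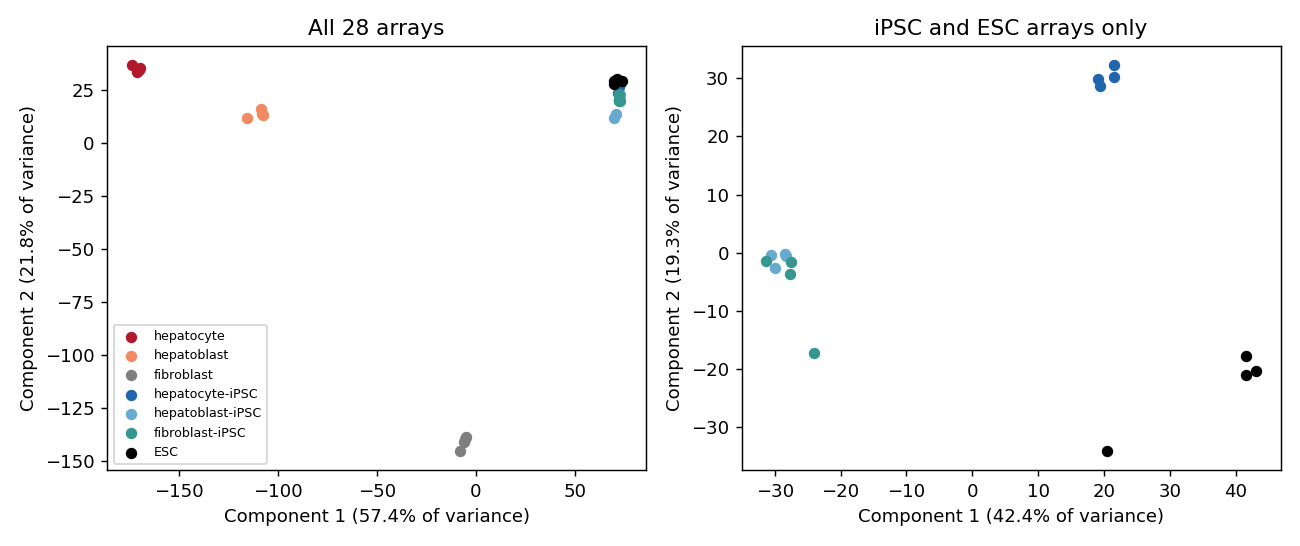
Principal components of normalized log2 signal, for all 28 arrays on the left (57.4% and 21.8% of the variance) and for the iPSC and ESC arrays on the right (42.4% and 19.3%); each point is an array, coloured by group. Donor groups separate on the left, and on the right hepatocyte-iPSC and ESC lie apart from the overlapping hepatoblast-iPSC and fibroblast-iPSC, with ESC array 1 away from the other ESC arrays.

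Values below are differences in log2 signal ± the standard error, with n = 4 arrays per group and adjusted p from limma. For each gene given as among the most changed of a comparison, the 4 arrays of either group all lay on 1 side of those of the other. The camera test of a gene list compared its members with all other genes at a preset correlation between genes. Of 120 list calls made over the 12 comparisons, none turned direction relative to all genes under the other 3 ways of scaling. A shift of arrays to a common 75th percentile in place of quantile normalization moved the median of all genes by −0.56 (hepatocyte-iPSC against hepatocytes) to 0.48 (hepatocytes against fibroblasts). Counts of list members adjusted over the list alone equalled those over all genes except where both are given.

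Hepatoblasts differed from hepatocytes in the products of fetal liver and of dividing cells. Transcripts of Dlk1, a surface marker of hepatoblasts, the imprinted H19 RNA and the growth factor Igf2 were at least 664-fold, 620-fold and 678-fold higher in hepatoblasts, and Afp (alpha-fetoprotein) was at least 415-fold higher. The major urinary protein genes Mup1, Mup2, Mup6 and Mup3, products of adult liver, were at least 864-fold, 846-fold, 766-fold and 722-fold lower in hepatoblasts. In all, 1922 genes were higher and 1435 lower in hepatoblasts (57.3% higher, and 49.4% with the percentile shift). Of 15 hepatoblast and fetal liver genes, 13 rose and none fell (adjusted p = 3.26e-09), with Gpc3 at least 267-fold higher. Cell cycle genes were higher in 21 of 25 cases (adjusted p = 1.49e-14), among them Mcm5 at 4.40 ± 0.15. Imprinted genes rose in 12 of 21 cases and fell in 1 (adjusted p = 2.69e-06), including Cdkn1c at 8.80 ± 0.26. Of 40 mature hepatocyte genes, 21 were lower and 1 higher (adjusted p = 3.26e-09), including the cytochrome P450 gene Cyp1a2, at least 311-fold lower. Glycolysis and hypoxia genes (8 of 20 higher, adjusted p = 6.2e-05) and endoderm genes (8 of 19 higher, adjusted p = 0.0106) also passed. These 6 lists and the erythroid list kept their calls with an estimated correlation.

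Blood cell markers moved with these lists. Erythroid genes were higher in hepatoblasts in 8 of 10 cases and lower in 1 (adjusted p = 6.6e-05), with the globin gene Hba-a1 at least 341-fold higher and Hbb-b1 at 5.19 ± 0.23. Leukocyte genes were higher in 13 of 22 cases and lower in 2 (adjusted p = 0.0157, adjusted p = 0.532 with an estimated correlation). The neutrophil genes S100a8 and Mpo were at least 149-fold and 26.6-fold higher, while Vsig4, a gene of liver macrophages, fell by 3.32 ± 0.29. Immediate early and stress genes were higher in 13 of 18 cases and lower in 3 (adjusted p = 0.000308, adjusted p = 0.0766 with an estimated correlation), Atf3 by 5.90 ± 0.20. Interferon response genes were lower in 11 of 18 cases and higher in 1 (adjusted p = 0.000153, adjusted p = 0.0726 with an estimated correlation). Cholesterol and lipid synthesis genes were higher in 11 of 20 cases and lower in 2 (adjusted p = 0.000561, adjusted p = 0.109 with an estimated correlation). Fibroblast and matrix genes (16 of 41 higher) and stellate and bile duct genes (6 of 12 higher) passed at adjusted p = 0.021 and adjusted p = 0.0421, and liver transcription factors (1 higher and 5 lower of 20) at adjusted p = 0.0482. With an estimated correlation these gave adjusted p = 0.422, adjusted p = 0.125 and adjusted p = 0.165.

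Hepatocytes differed from fibroblasts in 5079 genes, of which 2206 were higher. Genes of proteins secreted by liver were the most raised, with Apoc3 at least 1044-fold, Serpina1c 1023-fold, Fga 1003-fold, Mup1 972-fold and Serpina1e 916-fold higher. The most lowered were genes of matrix, contractile and other fibroblast products, with Fbln2 at least 617-fold, Acta2 609-fold, Thy1 570-fold, Col1a1 558-fold and Emp1 539-fold lower. All 40 mature hepatocyte genes tested were higher (adjusted p = 4.41e-30), as were 17 of 20 liver transcription factors (adjusted p = 4.8e-11), among them Hnf4a by 6.26 ± 0.14 and Foxa3 by 7.09 ± 0.14. Albumin (Alb) read 7.74 ± 0.266 (SD, n = 4) in hepatocytes and 8.92 ± 0.199 in hepatoblasts, against 4.59 ± 0.212 in fibroblasts, where no array detected it, and how well its probe performs was not tested. Of 41 fibroblast and matrix genes, 39 were lower (adjusted p = 5.08e-17). Cell cycle genes were lower in 22 of 25 cases (adjusted p = 1.6e-09), p53 targets in 11 of 16 with 2 higher (adjusted p = 0.000914) and imprinted genes in 11 of 21 with 2 higher (adjusted p = 0.00254). These 6 lists kept their calls with an estimated correlation. Leukocyte genes were lower in hepatocytes in 14 of 22 cases and higher in 3 (adjusted p = 0.0116, adjusted p = 0.623 with an estimated correlation), with Cd68 at −5.55 ± 0.29 and Fcer1g at −6.33 ± 0.35. Epithelial (7 higher, 1 lower of 16), glycolysis and hypoxia (2 higher, 10 lower of 20) and interferon response genes (7 higher, 2 lower of 18) passed at adjusted p = 0.00176, adjusted p = 0.0126 and adjusted p = 0.0167, and gave adjusted p = 0.102, adjusted p = 0.102 and adjusted p = 0.293 with an estimated correlation. The share of higher genes among the calls was 43.4%, and 62.3% with the percentile shift.

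Hepatoblasts differed from fibroblasts in 4447 genes, of which 2106 were higher. The largest rises were again in plasma protein genes, with Fga at least 1051-fold, Serpina1b 1017-fold, Apoa1 985-fold, Serpina1d 980-fold and Serpina1e 915-fold higher. Thy1 was at least 740-fold, the lysyl oxidase relative Loxl1 463-fold and Mgp (matrix Gla protein) 392-fold lower, and Lox and Tnc (tenascin C) fell by 9.18 ± 0.37 and 9.02 ± 0.38. Mature hepatocyte genes rose in 34 of 40 cases (adjusted p = 1.7e-22), liver transcription factors in 16 of 20 (adjusted p = 1.87e-09), and hepatoblast and fetal liver genes in 11 of 15 with 2 lower (adjusted p = 8.22e-05). All 10 erythroid genes were higher (adjusted p = 2.23e-07), Hba-a1 by at least 499-fold, and 9 of 16 epithelial genes (adjusted p = 7.28e-06), Krt8 by 8.67 ± 0.23. Fibroblast and matrix genes fell in 38 of 41 cases (adjusted p = 8.4e-20), and p53 targets in 12 of 16 with 2 higher (adjusted p = 5.91e-05). Cholesterol and lipid synthesis genes were higher in 8 of 20 cases (adjusted p = 0.00141, adjusted p = 0.173 with an estimated correlation), and the other 7 lists kept their calls. Leukocyte genes were not called as a list (6 higher and 13 lower of 22, adjusted p = 0.206), with S100a8 at least 218-fold higher and C1qb, a complement gene of macrophages, lower by a log2 difference of −5.26 ± 0.35. The share of higher genes was 47.4%, and 58.2% with the percentile shift.

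Reprogramming of hepatocytes was followed by loss of the liver programme and gain of the pluripotent one. Apoc3, Serpina1c, Ambp, Mup1 and Cyp2e1 were at least 1008-fold, 988-fold, 945-fold, 939-fold and 906-fold lower in hepatocyte-iPSC than in hepatocytes. Pou5f1 (Oct4) was at least 294-fold higher, and the most raised genes were Tubb2b, Esrrb, Dppa5a, Dnmt3l and Ooep, at least 483-fold, 493-fold, 516-fold, 454-fold and 379-fold higher. In all, 3560 genes were higher and 2366 lower. All 40 mature hepatocyte genes fell (adjusted p = 5.36e-28), as did 18 of 20 liver transcription factors with 1 higher (adjusted p = 2.22e-10). Pluripotency genes rose in 31 of 32 cases (adjusted p = 5.09e-15), cell cycle genes in 24 of 25 (adjusted p = 2.22e-10), glycolysis and hypoxia genes in 15 of 20 (adjusted p = 4.42e-05) and p53 targets in 12 of 16 with 2 lower (adjusted p = 0.0275). Examples were the glycolytic enzyme Pkm at 8.79 ± 0.16 and Cdkn1a at 3.75 ± 0.16. These 6 lists kept their calls with an estimated correlation. Interferon response genes (11 lower and 1 higher of 18, adjusted p = 0.0244) and cholesterol and lipid synthesis genes (11 lower and 4 higher of 20, adjusted p = 0.0403) gave adjusted p = 0.28 and adjusted p = 0.36 with an estimated correlation. Leukocyte genes were not called as a list (4 higher, 8 lower of 22). Higher genes were 60.1% of the calls, and 42.6% with the percentile shift.

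Hepatoblast-iPSC likewise lost liver transcripts, with Fga, Serpina1b, Ambp, Ttr and Serpina1e at least 979-fold, 947-fold, 944-fold, 870-fold and 853-fold lower than in hepatoblasts. Trh, Dnmt3l, Esrrb and Dppa4 were at least 731-fold, 389-fold, 357-fold and 308-fold higher, Dppa5a rose by 9.26 ± 0.17, and Pou5f1 was at least 262-fold higher. There were 2893 higher and 2185 lower genes. Mature hepatocyte genes fell in 34 of 40 cases (adjusted p = 1.7e-23), liver transcription factors in 16 of 20 with 1 higher (adjusted p = 8.14e-10), hepatoblast and fetal liver genes in 11 of 15 with 1 higher (adjusted p = 1.41e-05), and cholesterol and lipid synthesis genes in 16 of 20 (adjusted p = 1.03e-06). Pluripotency genes rose in 30 of 32 cases (adjusted p = 2.26e-16), and imprinted genes fell in 11 of 21 with 4 higher (adjusted p = 0.0239), Dlk1 by −8.22 ± 0.21. Erythroid genes fell in 7 of 10 cases with 1 higher (adjusted p = 0.000177), Hba-a1 by at least 465-fold. These 7 lists kept their calls with an estimated correlation.

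A further 11 lists passed in that comparison with the preset correlation and not with an estimated correlation. Leukocyte genes were lower in 17 of 22 cases and higher in 2 (adjusted p = 1.73e-05, adjusted p = 0.258 with an estimated correlation), S100a8 by at least 203-fold. Immediate early and stress genes were lower in 13 of 18 and higher in 2 (adjusted p = 0.000177, adjusted p = 0.0623 with an estimated correlation), Atf3 by at least 134-fold. Cell cycle genes (15 higher, 1 lower of 25) and mesoderm genes (7 higher of 12) passed at adjusted p = 0.000456 and adjusted p = 0.00345, and gave adjusted p = 0.0945 and adjusted p = 0.0623 with an estimated correlation. Glycolysis and hypoxia genes (10 higher, 2 lower of 20), fibroblast and matrix genes (23 higher, 5 lower of 41) and germline genes (5 higher of 15) passed at adjusted p = 0.0239, adjusted p = 0.0289 and adjusted p = 0.0289. With an estimated correlation they gave adjusted p = 0.0923, adjusted p = 0.417 and adjusted p = 0.0796. Ectoderm and neural (5 higher of 10), endoderm (5 higher, 8 lower of 19), sex-linked (4 lower of 5) and p53 target genes (7 higher, 2 lower of 16) passed between adjusted p = 0.0327 and adjusted p = 0.0477. With an estimated correlation these gave adjusted p = 0.0796, adjusted p = 0.0674, adjusted p = 0.0923 and adjusted p = 0.0764.

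Fibroblast-iPSC lost the fibroblast and matrix genes, of which 40 of 41 were lower than in fibroblasts (adjusted p = 7.21e-21). Examples were Col1a2, which fell by 7.93 ± 0.28, Tagln at −6.41 ± 0.22 and Col1a1 at −6.80 ± 0.37. Also among the most lowered were Igfbp5 at −7.58 ± 0.25, Ptn at −7.41 ± 0.35, Fcer1g at least 195-fold and Lyz2 (the lysozyme of macrophages) at −8.00 ± 0.42. Trh, Esrrb, Gldc and Dppa4 were at least 695-fold, 417-fold, 340-fold and 323-fold higher, Dppa5a rose by 10.15 ± 0.17, and Pou5f1 was at least 303-fold higher. There were 2666 higher and 2312 lower genes. Pluripotency genes rose in 28 of 32 cases with 1 lower (adjusted p = 4.02e-18), epithelial genes in 13 of 16 with 1 lower (adjusted p = 5.32e-06), Cdh1 (E-cadherin) by at least 65.4-fold, and p53 targets fell in 7 of 16 with 2 higher (adjusted p = 0.0135). These 4 lists kept their calls with an estimated correlation. Leukocyte genes were lower in 14 of 22 cases and higher in 1 (adjusted p = 1.57e-05, adjusted p = 0.28 with an estimated correlation), and immediate early and stress genes in 14 of 18 (adjusted p = 0.000663, adjusted p = 0.0945 with an estimated correlation). Cell cycle (18 higher, 5 lower of 25), germline (5 higher of 15), interferon response (8 lower of 18), sex-linked (4 lower of 5) and glycolysis and hypoxia genes (7 higher, 3 lower of 20) passed at adjusted p = 0.00234, adjusted p = 0.0154, adjusted p = 0.0237, adjusted p = 0.0304 and adjusted p = 0.0476. With an estimated correlation they gave adjusted p = 0.197, adjusted p = 0.0945, adjusted p = 0.246, adjusted p = 0.0945 and adjusted p = 0.197. Higher genes were 53.6% of the calls, and 64.7% with the percentile shift.

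Against ESC, hepatocyte-iPSC were higher in 382 genes and lower in 349. The core factors Pou5f1 and Nanog were not called (0.29 ± 0.11 and −0.56 ± 0.12), whereas Zfp42 (Rex1), a marker of naive pluripotency, fell by 3.06 ± 0.24 and Sox2 by 1.73 ± 0.28. The most raised genes included both lysozyme genes, Lyz2 at 3.08 ± 0.42 and Lyz1 at 3.05 ± 0.42, the collagenase Mmp13 at 2.77 ± 0.25, Prl2c3 at 3.06 ± 0.32, the imprinted adaptor Grb10 at 2.65 ± 0.23, Smtnl1 at 2.48 ± 0.19 and Ube2l6 at least 4.08-fold. Gpnmb rose by 2.24 ± 0.28, but by 0.64 as the mean of its probes, which is not past the fold threshold. The most lowered were Mid1 (−4.93 ± 0.44), Mmrn2 (−4.59 ± 0.20), Tex13b (−4.03 ± 0.14), Fam25c (−3.03 ± 0.20), Fmr1nb (−3.03 ± 0.29), Zc3h13 (−2.88 ± 0.53) and Ddx5 (−2.87 ± 0.46). Germline genes were lower in 4 of 15 cases (adjusted p = 3.52e-06), Rhox9 by −2.17 ± 0.16 and Rhox5 by −1.58 ± 0.23, both X-linked homeobox genes. Imprinted genes were lower in 6 of 21 and higher in 2 (adjusted p = 0.0234), including Impact at −1.40 ± 0.11 and Mest at −2.29 ± 0.21. Of 16 p53 targets, 1 was lower (adjusted p = 0.015), Plk2 at −1.20 ± 0.25. These 3 lists kept their calls with an estimated correlation. Ectoderm and neural genes were higher in 3 of 10 cases (adjusted p = 0.0336, adjusted p = 0.106 with an estimated correlation), Otx2 by 1.83 ± 0.16. Hepatoblast and fetal liver genes were higher in 1 and lower in 3 of 15 (adjusted p = 0.0411, adjusted p = 0.19 with an estimated correlation), including H19 at −1.28 ± 0.23. Leukocyte genes were not called as a list (3 higher of 22, adjusted p = 0.123), with Cd68 at 1.13 ± 0.29 beside the lysozymes. Of 40 mature hepatocyte genes, only Apoa2 was called, at 1.18 ± 0.17. Higher genes were 52.3% of the calls, and 16.1% of 1559 calls with the percentile shift.

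Hepatoblast-iPSC differed from ESC in 566 higher and 618 lower genes, with genes of the primitive streak and of matrix among the most raised. The streak genes rose, Fgf8 at least 43.4-fold and T (brachyury) by 4.54 ± 0.18, and the epiblast gene Fgf5 rose at least 20.2-fold. Col6a1 rose by 4.87 ± 0.38, Car4 (a carbonic anhydrase) by 4.79 ± 0.15, Acta2 (smooth muscle actin) by 4.41 ± 0.53, Mgp by 4.37 ± 0.32 and the interferon-inducible Gbp2 by 4.33 ± 0.25. The ESC arrays varied widely for Acta2 (6.36 ± 1.95, SD), so the size of its rise over ESC is uncertain, here and in fibroblast-iPSC. The interferon-stimulated genes Ifi27 and Usp18 fell by 4.92 ± 0.26 and 4.61 ± 0.31, and Oas2 was at least 29.1-fold lower. Mmrn2 and Tex13b were at least 30.5-fold and 19.2-fold lower, Fam25c was lower at −4.85 ± 0.20, Napsa at −4.20 ± 0.37, Zfp42 at −3.68 ± 0.24 and Sox2 at −2.60 ± 0.28. Pou5f1 and Nanog were not called (−0.26 ± 0.11 and −0.28 ± 0.12). Mesoderm genes were higher in 7 of 12 cases and lower in 1 (adjusted p = 1.69e-05), Gsc (goosecoid) by 4.17 ± 0.19, and p53 targets lower in 6 of 16 (adjusted p = 8.26e-06), Cdkn1a by −1.32 ± 0.16. Both lists kept their calls with an estimated correlation. Fibroblast and matrix genes were higher in 18 of 41 cases (adjusted p = 3.07e-06, adjusted p = 0.12 with an estimated correlation), Col1a1 by 3.99 ± 0.37 and Timp2 by 3.25 ± 0.32, while Thy1 was not called (0.22 ± 0.33). Interferon response genes were lower in 7 of 18 (adjusted p = 0.000418, adjusted p = 0.111 with an estimated correlation), and cholesterol and lipid synthesis genes higher in 4 and lower in 2 of 20 (adjusted p = 0.000751, adjusted p = 0.124 with an estimated correlation). Epithelial genes (3 higher of 16, adjusted p = 0.00494), pluripotency genes (2 higher, 7 lower of 32, adjusted p = 0.0309) and endoderm genes (5 higher, 1 lower of 19, adjusted p = 0.0443) gave adjusted p = 0.128, adjusted p = 0.0906 and adjusted p = 0.0906 with an estimated correlation. For ectoderm and neural genes (4 higher of 10, adjusted p = 0.018, adjusted p = 0.0906 with an estimated correlation) the median of −0.09 and the mean of 0.99 differed in sign, and the test pointed up.

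Fibroblast-iPSC were higher than ESC in 518 genes and lower in 598. Fgf5 and Fgf8 were at least 18.3-fold and 16-fold higher, Car4 rose by 4.48 ± 0.15, Enpp2 (autotaxin) by 3.93 ± 0.19, Rhox5 by 3.91 ± 0.23, Acta2 by 3.70 ± 0.53 and Zfp608 by 3.63 ± 0.27. Erdr1 was at least 282-fold lower, Mmrn2 29.9-fold, Oas2 28.6-fold and Tex13b 18.9-fold, and Mid1 (−5.65 ± 0.44), Ifi27 (−5.39 ± 0.26), Fam25c (−5.34 ± 0.20) and Usp18 (−5.26 ± 0.31) were lower as well. Zfp42 fell by 3.54 ± 0.24 and Sox2 by 1.98 ± 0.28, and Pou5f1 and Nanog were not called (−0.22 ± 0.11 and −0.34 ± 0.12). Of 16 p53 targets 4 were lower (adjusted p = 0.00658), Cdkn1a by −1.76 ± 0.16, and this list alone kept its call with an estimated correlation. Interferon response genes were lower in 7 of 18 cases (adjusted p = 3.69e-05, adjusted p = 0.0755 with an estimated correlation). Cholesterol and lipid synthesis genes were higher in 3 and lower in 1 of 20 (adjusted p = 0.000286, adjusted p = 0.117 with an estimated correlation). Ectoderm and neural genes were higher in 4 and lower in 1 of 10 (adjusted p = 0.00729, adjusted p = 0.0755 with an estimated correlation), and mesoderm genes higher in 4 and lower in 1 of 12 (adjusted p = 0.0318, adjusted p = 0.233 with an estimated correlation). Epithelial genes (5 higher, 1 lower of 16, adjusted p = 0.0176), fibroblast and matrix genes (9 higher, 1 lower of 41, adjusted p = 0.0176) and pluripotency genes (3 higher, 9 lower of 32, adjusted p = 0.0318) gave adjusted p = 0.233, adjusted p = 0.509 and adjusted p = 0.108 with an estimated correlation.

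Many genes differed from ESC in the same direction in more than 1 kind of iPSC. Hepatoblast-iPSC and fibroblast-iPSC shared 331 higher and 431 lower genes, against 24.6 and 31.1 expected of independent calls. Hepatocyte-iPSC shared 139 higher and 192 lower genes with hepatoblast-iPSC (18.2 and 18.1 expected) and 135 and 167 with fibroblast-iPSC (16.6 and 17.5 expected). All 3 kinds shared 105 higher and 143 lower genes, among them Grb10, higher, and Mmrn2, Tex13b, Fam25c and Zfp42, lower. The comparisons share the ESC arrays. With the ESC arrays split between them, hepatoblast-iPSC and fibroblast-iPSC shared 256 to 307 higher and 332 to 383 lower genes. The split removed the noise of shared arrays only, since all parts came from the same ESC group. A trait of these ESC would appear as sharing in each comparison, so the counts cannot tell it from traits shared by the iPSC.

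**Figure D2:**
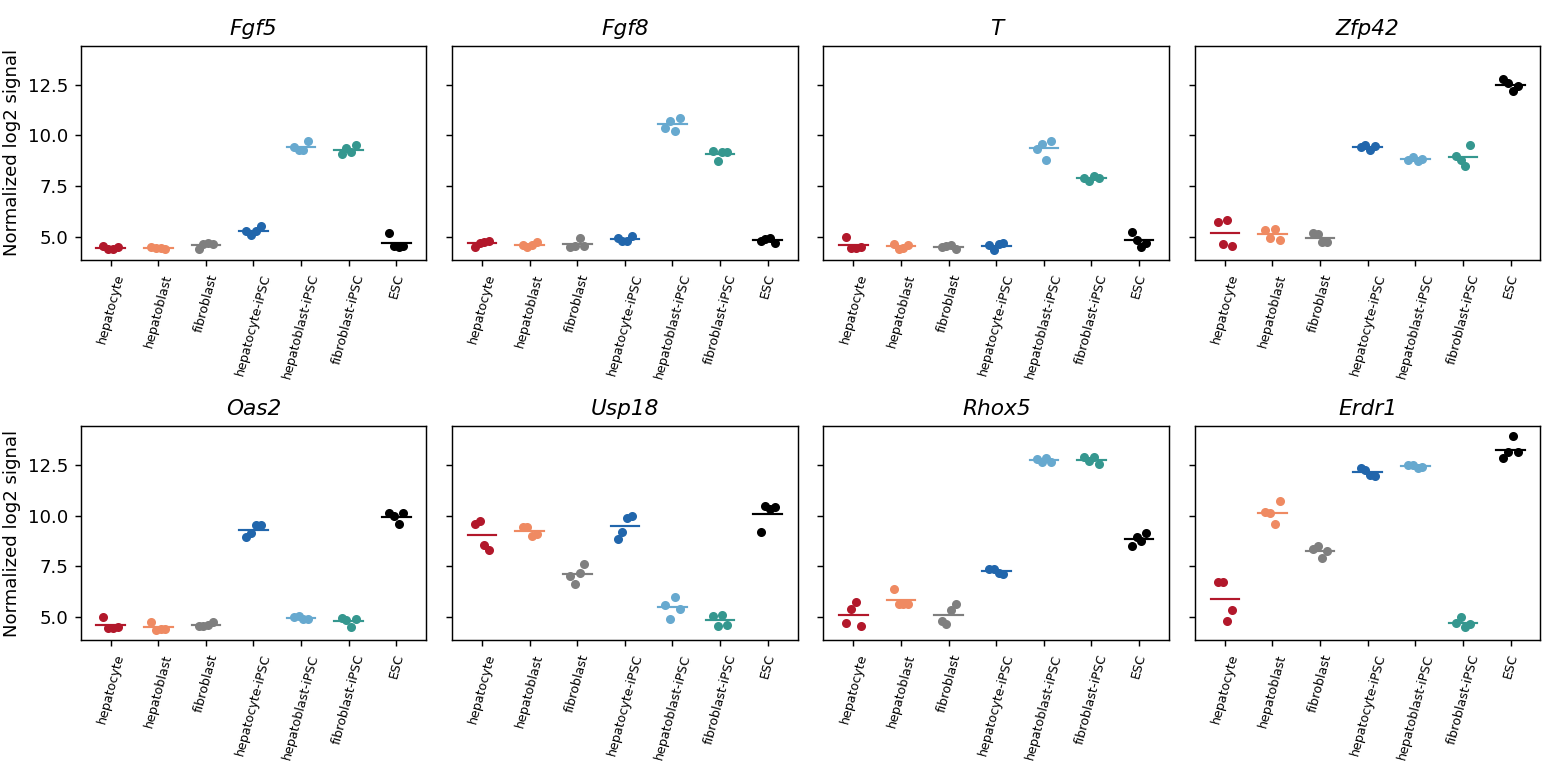
Normalized log2 signal of 8 genes in the 7 groups; points are arrays (4 per group) and lines are group means. Fgf5 lies between 9.08 and 9.73 in hepatoblast-iPSC and fibroblast-iPSC, and no higher than 5.55 in hepatocyte-iPSC, ESC and the donor cells.

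Hepatocyte-iPSC were compared with fibroblast-iPSC, as iPSC of a liver donor and of a non-liver donor. In all comparisons between iPSC, an effect of the donor kind cannot be told apart from traits of the particular iPSC profiled. Fgf5, Fgf8, Oas2 and Usp18 lay closer to fibroblast-iPSC than to hepatocyte-iPSC in hepatoblast-iPSC, which also have a liver donor. These genes therefore do not part liver from non-liver donors. There were 524 higher and 360 lower genes. Erdr1 was at least 130-fold higher. The interferon-stimulated genes Usp18 (4.64 ± 0.31), Oas2 (at least 18-fold) and Ifi27 (3.64 ± 0.26) were also among the most raised, with Napsa (4.18 ± 0.37), Myo1f (3.79 ± 0.41), Pdyn (prodynorphin, 3.68 ± 0.24) and Vax2 (at least 9.27-fold). The most lowered were Rhox5 (−5.49 ± 0.23), Car4 (−4.28 ± 0.15), Fgf8 (−4.19 ± 0.16), Fgf5 (−3.98 ± 0.17), Enpp2 (−3.63 ± 0.19), Rhox9 (−3.62 ± 0.16), Klhl13 (−3.55 ± 0.23) and Prickle1 (−3.44 ± 0.27). Interferon response genes were higher in 8 of 18 cases (adjusted p = 8.83e-07), glycolysis and hypoxia genes in 4 of 20 (adjusted p = 0.000389), Ndrg1 by 1.49 ± 0.19, and imprinted genes were lower in 6 of 21 with 1 higher (adjusted p = 0.00413), H19 by −1.74 ± 0.23. These 3 lists kept their calls with an estimated correlation. Cholesterol and lipid synthesis genes (3 lower of 20, adjusted p = 0.00513), hepatoblast and fetal liver genes (1 higher, 3 lower of 15, adjusted p = 0.00613) and mesoderm genes (1 higher, 4 lower of 12, adjusted p = 0.0064) gave adjusted p = 0.207, adjusted p = 0.0663 and adjusted p = 0.0936 with an estimated correlation. Germline genes (3 lower of 15, adjusted p = 0.00757) and fibroblast and matrix genes (2 higher, 8 lower of 41, adjusted p = 0.0231) gave adjusted p = 0.0663 and adjusted p = 0.431 with an estimated correlation. Leukocyte genes were higher in 4 of 22 (adjusted p = 0.0231, adjusted p = 0.617 with an estimated correlation), Cd68 by 2.55 ± 0.29 and Laptm5 by 2.38 ± 0.29, though the mean of the list was −0.12 with the percentile shift. Of 5 sex-linked genes 1 was higher (adjusted p = 0.0451, adjusted p = 0.132 with an estimated correlation), the Y-linked Eif2s3y by at least 6.55-fold. Mature hepatocyte genes were not called as a list (3 higher of 40, adjusted p = 0.661), with Trf (transferrin) at 2.16 ± 0.15, Fah at 1.89 ± 0.14 and Ass1 at 1.31 ± 0.17. Higher genes were 59.3% of the calls, and 17.6% of 2242 calls with the percentile shift.

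Hepatoblast-iPSC and fibroblast-iPSC differed least, in 103 higher and 30 lower genes. Erdr1 was at least 160-fold higher in hepatoblast-iPSC, Mid1 by 5.09 ± 0.44, Gbp2 by 3.11 ± 0.25, Gsc by 2.78 ± 0.19, Spink1 by 2.48 ± 0.34, Xlr4a by 2.33 ± 0.40, Sp5 by 2.29 ± 0.46 and Eif2s3y at least 3.48-fold. Insm1 (−1.88 ± 0.18), Aqp3 (−1.83 ± 0.28), Wnt7b (−1.37 ± 0.17), Cds1 (−1.36 ± 0.25) and Hes6 (−1.35 ± 0.19) were lower. Trp53i11 was lower at −1.33 ± 0.19, but at −0.91 without background correction, −0.94 in the authors' normalized values and −0.70 as the mean of its probes. The stress genes Ddit3 (−1.63 ± 0.43, adjusted p = 0.0273) and Nupr1 (−1.60 ± 0.44, adjusted p = 0.032) were called near the threshold. Ddit3 missed the threshold without any 1 of the 4 hepatoblast-iPSC arrays or fibroblast-iPSC arrays 2 or 3 (−1.43 to −1.71, adjusted p = 0.0537 to 0.105), and Nupr1 without any 1 of the 8 arrays (−1.49 to −1.70, adjusted p = 0.0509 to 0.101). Mesoderm genes were higher in 6 of 12 cases, and in 7 when adjusted over the list alone (adjusted p = 3.83e-13), with Mixl1 at 2.22 ± 0.18 and T at 1.48 ± 0.18. Endoderm genes were higher in 3 of 19, and in 4 adjusted over the list alone (adjusted p = 0.000373), Foxa2 by 1.58 ± 0.18, Sox17 by at least 2.15-fold and Gata6 by at least 3.48-fold. Of 5 sex-linked genes 2 were higher (adjusted p = 0.000679), and p53 targets shifted down with no member called (adjusted p = 0.00271). These 4 lists kept their calls with an estimated correlation. Fibroblast and matrix genes were higher in 5 of 41, and in 7 adjusted over the list alone (adjusted p = 8.82e-08, adjusted p = 0.0765 with an estimated correlation), Col3a1 by 1.80 ± 0.38. Glycolysis and hypoxia genes (1 higher of 20, adjusted p = 0.00426), erythroid genes (none called of 10, adjusted p = 0.0335) and hepatoblast and fetal liver genes (3 higher of 15, adjusted p = 0.0382), Dlk1 by 1.26 ± 0.21, gave adjusted p = 0.0636, adjusted p = 0.0636 and adjusted p = 0.133 with an estimated correlation. The mean of the erythroid list was −0.06 with the percentile shift. Of 13 endothelial genes, 2 were higher, and 3 adjusted over the list alone. Higher genes were 77.4% of the calls, and 58.5% with the percentile shift.

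Hepatoblast-iPSC against hepatocyte-iPSC set 2 stages of the same lineage side by side, with 349 higher and 467 lower genes. The most raised included the streak genes Fgf8 (5.63 ± 0.16), T (at least 20.1-fold) and Gsc (at least 18.4-fold), with Rhox5 (5.47 ± 0.23), the Wnt target Sp5 (5.39 ± 0.46), Car4 (4.59 ± 0.15), Mid1 (4.37 ± 0.44) and Mgp (4.34 ± 0.32). Oas2 was at least 18.3-fold lower, and Napsa (−4.22 ± 0.37), Usp18 (−3.99 ± 0.31), Pdyn (−3.39 ± 0.24), Mmp13 (−3.38 ± 0.25), Ifi27 (−3.17 ± 0.26), Vax2 (−3.08 ± 0.30) and Mapt (tau, −3.05 ± 0.20) were lower. Mesoderm genes were higher in 7 and lower in 1 of 12 (adjusted p = 1.79e-07). Hepatoblast and fetal liver genes were higher in 4 of 15 (adjusted p = 1.71e-05), with 1 lower when adjusted over the list alone, and included H19 at 2.21 ± 0.23, Krt8 at 1.85 ± 0.23 and Igf2 at 1.35 ± 0.19. Of 16 p53 targets 1 was lower (adjusted p = 0.0101), Gdf15 at −1.57 ± 0.25. These 3 lists kept their calls with an estimated correlation. Fibroblast and matrix genes were higher in 16 of 41 (adjusted p = 1.03e-07, adjusted p = 0.0617 with an estimated correlation), Ccn1 by 2.78 ± 0.22, and interferon response genes lower in 8 of 18 (adjusted p = 1.71e-05, adjusted p = 0.0617 with an estimated correlation). Leukocyte genes were lower in 5 of 22 (adjusted p = 0.0101, adjusted p = 0.486 with an estimated correlation), Lyz2 by −1.89 ± 0.42 and Laptm5 by −2.11 ± 0.29. Germline (3 higher, 1 lower of 15), imprinted (4 higher, 2 lower of 21) and endoderm genes (4 higher, 2 lower of 19) passed at adjusted p = 0.0143, adjusted p = 0.0326 and adjusted p = 0.0334, each with adjusted p = 0.0617 with an estimated correlation. Cholesterol and lipid synthesis (1 higher of 20) and glycolysis and hypoxia genes (1 lower of 20) passed at adjusted p = 0.00663 and adjusted p = 0.0367, and gave adjusted p = 0.192 and adjusted p = 0.184 with an estimated correlation. Epithelial genes were higher in 3 and lower in 1 of 16 (2 lower adjusted over the list alone). Higher genes were 42.8% of the calls, and 56.5% with the percentile shift.

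Trophoblast and endothelial genes passed as lists in none of the 12 comparisons, at the preset or the estimated correlation. Of the two-cell stage list only the translation factor Eif1a was tested, and it rose in hepatocyte-iPSC and hepatoblast-iPSC over their donors (1.47 ± 0.14 and 1.19 ± 0.14) and fell in hepatocytes against fibroblasts by 1.09 ± 0.14.

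Donor memory was tested with the genes that mark each donor. The hepatocyte signature of 987 genes read 6.17 ± 0.00259 (SD, n = 4) in hepatocyte-iPSC and 6.06 ± 0.0180 (n = 8) in the other iPSC (exact permutation p = 0.00202). That p is the smallest that 4 against 8 arrays allow. The signature read 9.59 ± 0.0220 in hepatocytes and 6.14 ± 0.0583 in ESC. ESC arrays 2, 3 and 4 each read 6.17, the level of hepatocyte-iPSC, and the far ESC array 1 read 6.05. Hepatocyte-iPSC thus did not stand above these ESC arrays, while the other iPSC lay below them. Its median difference was 0.04, with 54 genes higher (5.47%, against 3.87% of other genes) and 17 lower (1.72%, against 2.76%). Set against all other genes by camera, the signature passed before adjustment, at 0.0468, but not over the 5 signature tests (adjusted p = 0.234, adjusted p = 0.635 with an estimated correlation). The hepatoblast signature of 773 genes did not differ detectably as a set in hepatoblast-iPSC (median −0.02, adjusted p = 0.772, exact permutation p = 0.448), nor did the fibroblast signature of 1813 genes in fibroblast-iPSC (median −0.01, adjusted p = 0.979, exact permutation p = 0.406). Their called members went both ways, 2.20% higher and 1.81% lower for the hepatoblast signature (1.04% and 0.827% of other genes) and 1.49% and 2.21% for the fibroblast signature (0.625% and 1.46%). Hepatocyte-iPSC also read highest for the hepatoblast signature, at 7.51 ± 0.0122, against 7.45 ± 0.0170 in hepatoblast-iPSC and 7.43 ± 0.0168 in fibroblast-iPSC. Their higher level was thus not confined to genes of their own donor. For the fibroblast signature hepatocyte-iPSC (7.50) lay between hepatoblast-iPSC (7.52) and fibroblast-iPSC (7.48). The shared hepatic signature of 1288 genes had a median of 0.02 in hepatocyte-iPSC against fibroblast-iPSC (adjusted p = 0.772), and its level per array gave an exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow. In hepatoblast-iPSC against fibroblast-iPSC the median was −0.01 and the mean 0.00 (adjusted p = 0.772, exact permutation p = 0.857). Against ESC, none of the 9 tests of a donor signature in a kind of iPSC passed with limma's camera (adjusted p = 0.33 to 0.831). With the percentile shift, which moved all genes, the medians were −0.24 for the hepatocyte signature and 0.14 for the fibroblast signature in their iPSC (−0.02 and −0.04 relative to all genes with members chosen anew under the shift, −0.20 and −0.03 with the members above). Those of the shared signature were −0.45 in hepatocyte-iPSC and −0.29 (adjusted p = 0.0403) in hepatoblast-iPSC (−0.19 and −0.16 relative to all genes with members chosen anew, −0.07 and −0.08 with those above).

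**Figure D3:**
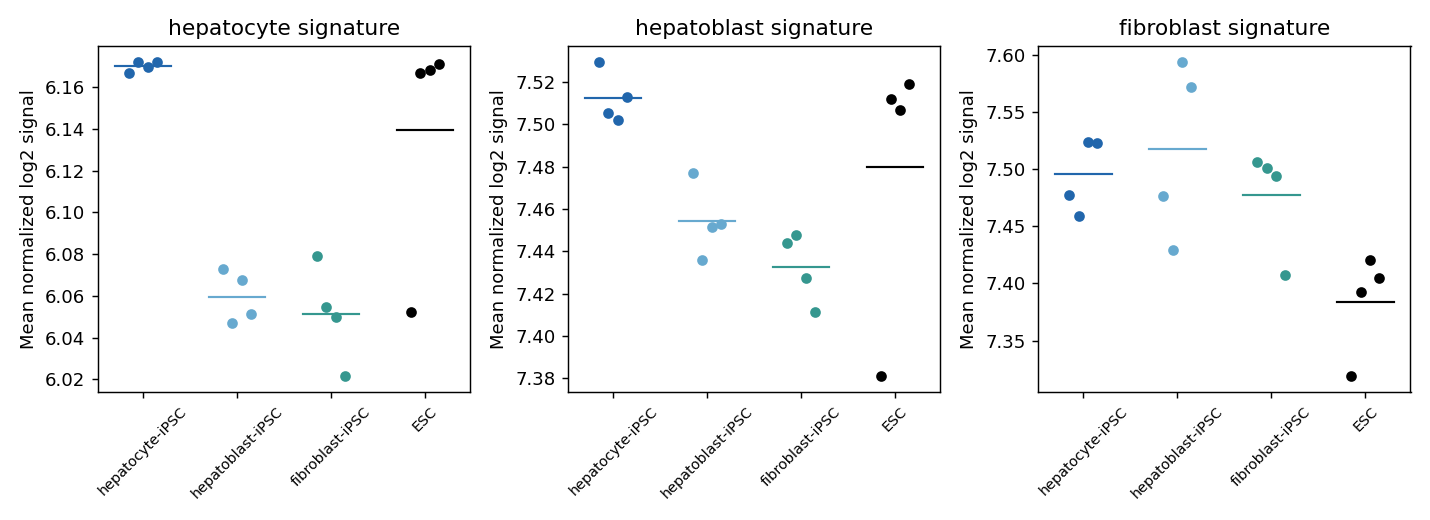
Mean normalized log2 signal of the hepatocyte, hepatoblast and fibroblast signatures in each iPSC and ESC array; points are arrays (4 per group) and lines are group means. The hepatocyte signature is at 6.17 in hepatocyte-iPSC and 6.06 and 6.05 in hepatoblast-iPSC and fibroblast-iPSC, with ESC at 6.14. ESC arrays 2, 3 and 4 are each at 6.17 and ESC array 1 is at 6.05.

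Genes that stood above ESC in a donor and also in its iPSC were counted as retained. The count did not ask whether the level of the donor was kept, so it also holds genes that read higher in the iPSC than in the donor. Hepatocyte-iPSC retained 114 hepatocyte genes (79.0 expected, a ratio of 1.44), among them Lyz2, Lyz1, Phlda1 at 2.14 ± 0.26, Mrps27 at 2.23 ± 0.18, Ube2l6 and Trim56 at 1.87 ± 0.23. Of these, Lyz2, Lyz1 and Mrps27 read higher in hepatocyte-iPSC than in hepatocytes, and Phlda1, Ube2l6 and Trim56 lower. Lyz2 and Lyz1 read far higher in fibroblasts (14.37 and 14.97) than in hepatocytes or hepatocyte-iPSC, so these 2 genes do not mark the hepatocyte donor. Lyz2 is the lysozyme of macrophages, and the leukocyte list varied between the hepatocyte arrays (SD 0.457). Whether leukocyte RNA gave the lysozyme signal of the hepatocyte arrays was not tested. Hepatoblast-iPSC retained 199 hepatoblast genes (109.0 expected, 1.83), among them Col6a1, Gbp2, Col1a1, Prickle1, the chemokine Cxcl12 at 3.78 ± 0.24 and Enpp2. Col6a1, Gbp2, Col1a1 and Prickle1 read higher in hepatoblast-iPSC (9.96, 10.2, 8.99 and 9.50) than in hepatoblasts (7.03, 8.34, 6.31 and 6.67). Cxcl12 and Enpp2 read lower (9.47 and 8.53 against 11.8 and 9.52). Fibroblast-iPSC retained 224 fibroblast genes (103.9 expected, 2.16), among them Enpp2, Acta2, Zfp608, Prickle1 and the intermediate filament gene Nes at 3.41 ± 0.24. Enpp2 and Zfp608 read higher in fibroblast-iPSC than in fibroblasts, and Acta2, Prickle1 and Nes lower. Genes of other donors gave ratios above and below those of the own donor. In hepatocyte-iPSC the ratio was 1.86 for hepatoblast genes and 2.05 for fibroblast genes (157 genes), both above the 1.44 of hepatocyte genes. In hepatoblast-iPSC it was 2.46 for fibroblast genes (279 genes), above the 1.83 of hepatoblast genes, and 1.495 for hepatocyte genes. In fibroblast-iPSC it was 1.29 for hepatocyte genes and 1.60 for hepatoblast genes, both below the 2.16 of fibroblast genes. For these higher genes, the own donor thus had the highest ratio only in fibroblast-iPSC. Fibroblast genes ranked first in hepatocyte-iPSC (2.05), hepatoblast-iPSC (2.46) and fibroblast-iPSC (2.16) alike, so their rank was not particular to fibroblast-iPSC. Genes below ESC in both numbered 213 for hepatocytes (2.12), 393 for hepatoblasts (2.67) and 355 for fibroblasts (2.65). For these lower genes another donor gave a higher ratio than the own donor in each kind of iPSC. In hepatocyte-iPSC the ratio was 2.40 for hepatoblast and 2.45 for fibroblast genes. It was 2.22 for hepatocyte and 2.74 for fibroblast genes in hepatoblast-iPSC, and 2.23 for hepatocyte and 2.68 for hepatoblast genes in fibroblast-iPSC. With the ESC arrays split between the comparisons, the median ratios of the own donor were 1.27, 1.71 and 2.04 for the higher genes and 1.96, 2.45 and 2.46 for the lower ones. All parts of the split came from the same ESC group, so traits of these ESC still entered both comparisons. Without background correction the retained higher genes numbered 35, 121 and 137 for hepatocyte, hepatoblast and fibroblast, with 42, 126 and 144 in the authors' normalized values.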

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

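Of the tests in this part, those of abundant fibroblast transcripts, the fit without hepatoblast-iPSC arrays 3 and 4 and the count of X-linked genes below the median were chosen only after the result was seen. The tests of genes by chromosome were not part of the fixed plan and were added once the data were in use. Among 210 groups of 4 arrays, 20 held an array far from the other 3 by Dixon's test, and chance marks about 1 in 20 groups. Values in this paragraph are mean log2 signals of a list or signature in the far array. Among hepatocytes these were array 3 for epithelial (7.07) and fibroblast and matrix genes (5.56), array 1 for imprinted genes (6.03) and array 4 for leukocyte genes (5.77). Hepatoblast array 3 lay apart for fibroblast and matrix genes (6.34). Fibroblast array 2 lay apart for ectoderm and neural (5.51), interferon response (6.90) and sex-linked genes (6.87), and for the hepatocyte (5.92) and fibroblast signatures (9.25), and fibroblast array 1 for endoderm genes (7.53). Among iPSC, far arrays were hepatoblast-iPSC 3 for glycolysis and hypoxia genes (11.1), fibroblast-iPSC 2 for the two-cell stage gene (11.7) and fibroblast-iPSC 4 for the fibroblast signature (7.41). ESC array 1 deviated from the mean of the other 3 by a root mean square of 0.587, and lay apart for immediate early and stress genes (7.37), mesoderm genes (5.76) and the hepatocyte (6.05), hepatoblast (7.38) and shared hepatic signatures (6.93).

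Some genes were called in opposite directions against ESC in 2 kinds of iPSC, and since they were chosen for that, a difference between these kinds followed from the choice. Hepatocyte-iPSC minus fibroblast-iPSC was −5.49 for Rhox5, 3.79 for Myo1f, 3.68 for Pdyn, 3.67 for Vax2, −3.62 for Rhox9, −3.55 for Klhl13, −2.87 for Wnt7b and 2.71 for Mapt. Hepatoblast-iPSC minus hepatocyte-iPSC was 5.47 for Rhox5, 5.39 for Sp5, −2.88 for Myo1f, −3.39 for Pdyn, −3.08 for Vax2, 3.33 for Rhox9, 3.29 for Klhl13 and −3.05 for Mapt.

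Fibroblast and matrix genes were higher in hepatoblast-iPSC than in ESC at the preset correlation but not with an estimated correlation (adjusted p = 0.12), and RNA carried over from fibroblasts was weighed. The 18 list members called higher reached a median of 3.08% of the fibroblast signal (interval 1.92% to 4.01%). Of 34 other abundant fibroblast transcripts, 8 stayed below 0.640% on all 4 arrays. Among these, Fcer1g, C1qb, C1qc and Lyz2 (0.211%) are leukocyte genes, and Thy1 (0.170%) had a variable ESC level (8.06 ± 1.12, SD). The rest were Igfbp5 (−0.148%), Thbs1 (0.00543%) and Col1a2 (0.217%). The level of 0.640% was set from members chosen for being called higher, so lower values elsewhere were partly built in. The test therefore cannot decide on carry-over as the whole cause. The median of the 34 was 0.881% (0.518% to 1.87%), but that of the 12 brightest was 2.03% (0.852% to 2.84%). Carry-over in whole or in part, or cells of another make-up than the fibroblasts profiled, stayed open, although the labels describe the iPSC as sorted on magnetic beads. Arrays 3 and 4 read higher for the list (7.89 and 7.67) than arrays 1 and 2 (7.06 and 6.98). Without arrays 3 and 4, 11 members were called (adjusted p = 0.00046, adjusted p = 0.133 with an estimated correlation), so these arrays carried part of the pattern and not its call at the preset correlation. Without arrays 1 and 2, 19 members were called higher (adjusted p = 4.32e-13, adjusted p = 0.00307 with an estimated correlation). With an estimated correlation the list thus passed when arrays 3 and 4 stood for the group. The preset correlation is meant in what follows. Without any 1 array the highest adjusted camera p at the preset correlation was 1.51e-05, and no biological explanation was tested.

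X-linked genes were lower in all 3 kinds of iPSC than in ESC, by medians of −0.41, −0.35 and −0.36 relative to all genes in hepatocyte-iPSC, hepatoblast-iPSC and fibroblast-iPSC (334 genes, adjusted p = 2.62e-17, adjusted p = 7.07e-07 and adjusted p = 1.15e-07, and adjusted p = 0.000564, adjusted p = 0.0327 and adjusted p = 0.0325 with an estimated correlation). The comparisons share the ESC arrays and no X-linked shift was called between iPSC (adjusted p = 0.234 to 0.994), so they count as 1 difference between ESC and iPSC and not as 3. A few strongly changed genes do not move a median by this much. At least 72.2% of X-linked genes lay below the median of all genes in each group, which largely restates the shift and is no separate test of it. ESC array 1 was excluded (−0.32 closest to 0 without it), as were the scaling and background correction (−0.29 closest to 0 in 3 other scalings). The design holds no group that separates a biological explanation, and none was tested.

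Chromosome 11 genes were higher in hepatoblast-iPSC than in fibroblast-iPSC, by a median of 0.19 relative to all genes (868 genes, adjusted p = 2.84e-10, adjusted p = 2e-09 with an estimated correlation). With the genes of the chromosome divided in map order into 2 equal parts, the lower median was 0.190, which excluded a few neighbouring genes. A higher dose of the whole chromosome in hepatoblast-iPSC could not be decided, since hepatoblast-iPSC minus hepatocyte-iPSC was 0.0915, between the bounds set for either answer. By camera that difference gave adjusted p = 0.225, and adjusted p = 0.00473 with an estimated correlation. Against ESC the median in hepatoblast-iPSC was 0.129 (adjusted p = 0.0137, adjusted p = 0.000352 with an estimated correlation). Arrays of hepatoblast-iPSC lay 0.128 to 0.153 above the ESC mean, those of hepatocyte-iPSC 0.0445 to 0.0716 and those of fibroblast-iPSC −0.0339 to 0.0019.

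Relabelling the arrays tested whether any grouping gave as many calls. In each of the 12 comparisons 1 of 35 splits of the 8 arrays, the real one, gave as many, and the highest count of any other split was 0. Each other split mixed the groups compared, so a difference between them widened the spread and left few calls to be made. Nor can the splits tell an effect of the cell kind from other traits shared by all arrays of a group. The real counts, fitted on those 8 arrays, were 727, 1174 and 1088 for hepatocyte-iPSC, hepatoblast-iPSC and fibroblast-iPSC against ESC. Between iPSC they were 893 for hepatocyte with fibroblast, 140 for hepatoblast with fibroblast and 822 for hepatoblast with hepatocyte. Against their donors the iPSC gave 5927, 5065 and 4969, and the donors gave 3326 (hepatoblast with hepatocyte), 5058 (hepatocyte with fibroblast) and 4415 (hepatoblast with fibroblast). For the hepatocyte signature, 4 of 100 drawn splits gave a camera p as small as the real one of 0.0506 (smallest other 0.0452). For the hepatoblast and fibroblast signatures 28 and 91 of 100 did (real 0.494 and 0.908, smallest other 0.171 and 0.000537). For the shared hepatic signature 4 of 35 did in hepatocyte-iPSC (0.42, smallest other 0.3) and 4 of 35 in hepatoblast-iPSC (0.507, smallest other 0.358).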

How the results depend on the processing

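The fit without ESC array 1 and fibroblast array 2 was chosen only after the data were seen. Of the values of named genes under the alternatives, 5238 kept direction and side of the threshold, 32 missed it, 12 newly passed it and 0 reversed. Without background correction, 415 genes were called in hepatocyte-iPSC against ESC, 76 in hepatoblast-iPSC against fibroblast-iPSC and 543 in hepatoblast-iPSC against hepatocyte-iPSC, and retained higher genes of hepatocytes, hepatoblasts and fibroblasts numbered 35, 121 and 137. The authors' normalized values gave 446 and 79 calls for the first 2 of these comparisons and 42, 126 and 144 retained genes. The 75th percentile shift gave 1559 calls in hepatocyte-iPSC against ESC, more than the 1175 in hepatoblast-iPSC against ESC, and 2242 in hepatocyte-iPSC against fibroblast-iPSC. It moved the median of the hepatocyte signature in hepatocyte-iPSC to −0.24, of the fibroblast signature in fibroblast-iPSC to 0.14, and of the shared hepatic signature to −0.45 in hepatocyte-iPSC and −0.29 (adjusted p = 0.0403) in hepatoblast-iPSC against fibroblast-iPSC. The shift itself moved the median of all genes, by −0.29 in hepatocyte-iPSC against ESC and −0.28 in hepatocyte-iPSC against fibroblast-iPSC. Relative to all genes these 4 medians were −0.02, −0.04, −0.19 and −0.16, and with the members of the main signatures −0.20, −0.03, −0.07 and −0.08; the cause of the part left was not tested, nor that of the changes without background correction or in the authors' values. An adjusted p below 0.05 alone, which calls more genes by construction, gave 2947, 3800 and 3459 for hepatocyte-iPSC, hepatoblast-iPSC and fibroblast-iPSC against ESC. Between iPSC it gave 2673 (hepatocyte with fibroblast), 497 (hepatoblast with fibroblast) and 2569 (hepatoblast with hepatocyte). It gave 7817 and 7666 for hepatoblast-iPSC and fibroblast-iPSC against their donors, and 6392 (hepatoblast with hepatocyte), 7796 (hepatocyte with fibroblast) and 7311 (hepatoblast with fibroblast) between donors. Retained higher and lower genes were then 565 and 806 for hepatocytes, 782 and 1166 for hepatoblasts, and 802 and 1030 for fibroblasts. An adjusted p below 0.001 left 67 calls in hepatoblast-iPSC against fibroblast-iPSC. With only detected members, the hepatocyte signature in hepatocyte-iPSC had a median of 0.15 (adjusted p = 0.0088) and the shared signature in hepatoblast-iPSC 0.000794, but a rise in the group tested can itself bring a member past that filter. With the 100 members of largest donor fold, medians were −0.0122 for the hepatocyte signature, 0.00369 for the fibroblast signature and −0.0111 for the shared signature in hepatocyte-iPSC. The fry test, which asks whether members changed at all and not whether they changed more than other genes, passed for the hepatocyte signature at the median of 0.0365 (adjusted p = 0.00111). Camera with an estimated correlation passed 3, 2 and 1 lists for hepatocyte-iPSC, hepatoblast-iPSC and fibroblast-iPSC against ESC. It left 3 for hepatocyte-iPSC against fibroblast-iPSC, 4 for hepatoblast-iPSC against fibroblast-iPSC and 3 for hepatoblast-iPSC against hepatocyte-iPSC. It left 7 and 4 for hepatoblast-iPSC and fibroblast-iPSC against their donors, and 7 for hepatoblasts against hepatocytes. For hepatocytes against fibroblasts it left 6. Leaving out each array gave 698 to 801, 1134 to 1424 and 1043 to 1255 calls for the 3 iPSC against ESC, and 863 to 914, 110 to 145 and 794 to 833 between iPSC in the order above. Without ESC array 1 and fibroblast array 2 the calls against ESC were 802, 1425 and 1256. With a replicate block the calls against ESC were 733, 1186 and 1116, which changed no count by over 1.5 times; correlations of samples with the same number ran from −0.184 to 0.197, so the numbers were not read as pairs. A beadchip block was not run because no beadchip identifiers were found. Signal over background limits what dim transcripts can show.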

Other observations

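Some sex-linked transcripts differed between the pluripotent groups. The Y-linked translation factor Eif2s3y, log2 8.77 in ESC, 7.83 in hepatocyte-iPSC and 6.92 in hepatoblast-iPSC, was detected on 0 of 4 fibroblast-iPSC arrays (4.50). Erdr1, at 13.3 in ESC, 12.1 in hepatocyte-iPSC and 12.4 in hepatoblast-iPSC, was likewise detected on 0 fibroblast-iPSC arrays (4.72), and Mid1 was at 11.2 in ESC, 10.6 in hepatoblast-iPSC, 6.26 in hepatocyte-iPSC and 5.54 in fibroblast-iPSC. Xist, the RNA that coats the inactive X chromosome, was at 9.25 in hepatoblasts and 7.11 in fibroblasts, and between 4.84 and 5.35 in the pluripotent groups. The Y-linked helicase Ddx3y was detected on all 4 fibroblast-iPSC arrays (8.03, against 8.43 in ESC), and neither Xist nor Ddx3y was called between pluripotent groups.

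Leukocyte genes had a mean level of 8.97 ± 0.0717 (SD, n = 4) in fibroblasts, 8.08 ± 0.962 in hepatoblasts, 6.45 ± 0.457 in hepatocytes, 6.17 ± 0.129 in hepatocyte-iPSC and 5.59 ± 0.0893 in ESC. The erythroid list had a mean level of 8.80 ± 0.0709 in hepatoblasts.

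The tests by chromosome, and the correlations between comparisons, were not part of the fixed plan and were added once the data were in use. Chromosome 19 genes were higher in all 3 kinds of iPSC than in ESC, by medians of 0.21, 0.21 and 0.20 relative to all genes (365 genes, adjusted p = 5.87e-06, adjusted p = 0.000108 and adjusted p = 2.14e-05). The estimated correlation gave adjusted p = 2.42e-05, adjusted p = 0.000144 and adjusted p = 5.15e-05. The comparisons share the ESC arrays and no chromosome 19 shift was called between iPSC (adjusted p = 0.857 to 0.994), so they count as 1 difference between ESC and iPSC. Chromosome 2 genes were also higher in all 3 kinds at the preset correlation (adjusted p = 0.00591, 0.0284 and 0.012), but not with an estimated correlation (adjusted p = 0.0821, 0.151 and 0.103). At the preset correlation chromosome 12 genes were lower in hepatocyte-iPSC (−0.166, adjusted p = 0.000159) and hepatoblast-iPSC (−0.128, adjusted p = 0.0284). Chromosome 13 genes were higher in hepatoblast-iPSC (0.152, adjusted p = 0.0137) and fibroblast-iPSC (0.130, adjusted p = 0.012). With an estimated correlation these gave adjusted p = 0.114, 0.353, 0.151 and 0.188. Differences from ESC correlated across genes at 0.864 between hepatoblast-iPSC and fibroblast-iPSC, 0.552 between hepatocyte-iPSC and hepatoblast-iPSC and 0.515 between hepatocyte-iPSC and fibroblast-iPSC, and sharing the ESC arrays alone gave 0.502 in simulated unchanged groups. The covariances were 0.362, 0.186 and 0.170 in the same order, against 0.0241, 0.0239 and 0.0239 in the simulated groups.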
